A study of Homo sapiens with 8 samples.

How the data were processed

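The data are gene counts from polyA RNA sequencing of human T cells, negatively selected from the blood of 4 healthy donors and stimulated with CD3/CD28 beads for 48 h with DMSO or the PRMT5 inhibitor C220. Per the labels' protocols, RNA integrity numbers were above 7, libraries were made with the TruSeq RNA kit and sequenced as 50 bp paired ends on an Illumina HiSeq instrument. Per the labels' protocols, reads were aligned to GRCh38 with HISAT2 and counted per gene with featureCounts on GENCODE 27. The deposited values are raw counts per gene; tool versions, the use of strand and whether reads or read pairs were counted are not given in the sources used here. edgeR is also named in the submitters' processing notes, with no role given. Because strand use is not stated, reads of genes that overlap on opposite strands, such as CMPK2 and RSAD2, cannot be told apart. Counts of near-identical copies, such as IFITM1, IFITM2 and IFITM3 or NBPF19, are uncertain.

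The table held 58395 genes, of which 20376 had no count. Columns without a sample numbered 0. Genes on the Y chromosome, XIST and TSIX were removed before any test (511 genes). Genes with a mean of at least 20 counts were kept, the minimum the labels' protocols state, which left 13706 genes, 11647 of them protein-coding. Gene names, types and positions came from GENCODE 44, which matched 13631 of the tested genes. Total counts ran from 12576088 to 20458129 per library, and a count of 3, taken as the floor, equals 0.147 to 0.239 CPM. Intervals and floors cover counting error only.

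Samples were grouped by the treatment in their labels. The main test was the edgeR quasi-likelihood F-test without a donor block, with TMM normalization, two-sided, and Benjamini-Hochberg adjustment at 0.05 (edgeR 4.0.16, R 4.3.3). Per gene, mean TMM-scaled CPM and SD over 4 libraries are given. Of 29 gene lists fixed before the data were examined, the 24 with at least 5 members tested were compared by camera on log2 CPM with a prior count of 2, a trended variance and a preset correlation of 0.01 (limma 3.58.1), adjusted over these 24 lists. Members were also counted over all genes tested and adjusted over the list alone. The mean change of the interferon-stimulated list within donors was tested by an exact sign-flip permutation test.

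The donor numbers in the labels pair the libraries, and the pairing rests on them. Deviations from the group means correlated, across genes, at 0.678 in donor A, 0.553 in donor B, 0.707 in donor C and 0.46 in donor D. The highest value between different donors was 0.609, and 1 of the 4 DMSO libraries was closer to the C220 library of another donor than to that of its own. A fit with the donor as a replicate block was run beside the main one; it called 29 members of the interferon-stimulated list lower in place of 4, adjusted over the list alone. Within groups, the most alike libraries still differed by a chi-square of 11.4 per gene, so none was a repeat of another.

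Other settings were RLE, upper-quartile and library-size scaling, no filter and a minimum mean of 100 counts, DESeq2 1.42.0 with and without the block, limma-voom, leaving out each donor or library, a fold minimum of 2, an adjusted p of 0.01, an estimated correlation, fry, a prior count of 0.5, and, chosen after seeing the data, a robust fit, the removal of each library's trend on gene length and GC content by splines with 5 degrees of freedom in the blocked fit, and camera and fry variants with the block.

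Genes named in the text were to be 10 fixed genes (PRMT5, WDR77, CLNS1A, IFNG, IL2, TNF, IRF7, CDKN1A and MKI67, and 1 that is not reported here), the 5 largest rises and 5 largest falls among called protein-coding genes with at least 1 CPM and the same direction in all 4 donors, and the leading called members of each list. Since edgeR called no gene, the last 2 parts used DESeq2 calls with the replicate block and calls adjusted over the list alone, a change made after values were seen. ISG15, MX1, CMPK2, IFI6, EOMES, RORA, PRDM1, CRTAM, CCR4, CCL20, ICAM1, GAA, TNFSF4 and others beyond the rule were chosen after their values were seen.

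The fits were tested on simulated counts with the real donor levels and depths, 200 genes changed and 13440 genes run. edgeR without the block recovered 0% of genes changed 1.5-fold, 1.49% of those changed 2-fold and 59.1% of those changed 4-fold, with 0 false calls. With the replicate block it recovered 7.46%, 68.7% and 95.5%, with 8 false calls among 144. DESeq2 with the block recovered 19.4%, 77.6% and 90.9%, with 27 false calls among 180. The simulated genes varied more evenly than the real ones (prior degrees of freedom 19.7 against 5.59 in the blocked fit), so these shares need not hold for the real counts. A list of 58 genes shifted by -0.7 on the log2 scale gave a camera p of 2.55e-38, and 0 of 20 draws without a shift had a p under 0.05, but the simulation holds no correlation between genes within a donor beyond their shared donor levels.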

Results

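Gene expression was measured by polyA RNA sequencing in T cells purified from the blood of 4 healthy donors, called donors A to D here. The cells were stimulated through CD3 and CD28 with antibody-coated beads for 48 h, a standard way to mimic antigen recognition, in the presence of either the vehicle DMSO or C220, an inhibitor of PRMT5. PRMT5 is an enzyme that places symmetric dimethyl marks on arginine residues of histones, splicing factors and other proteins. Each donor gave 1 library per treatment, so the groups held 4 DMSO and 4 C220 libraries. Total counts per library ran from 14944755 to 18615147 in DMSO and from 12576088 to 20458129 in C220. The comparison of C220 with DMSO asks how PRMT5 inhibition alters the transcriptome of activated T cells, and in particular their interferon response.

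Interferon-stimulated genes, a list of antiviral and signalling genes that type I interferon induces, fell in C220. Of the 58 members tested, 55 had a log2 fold change below 0 and 36 were lower in C220 in 4 of 4 donors. IFIT1, which binds viral RNA lacking host cap marks, had 4.33 ± 2.17 CPM in DMSO and 0.60 ± 0.38 CPM in C220 (SD, n = 4). Its value in the C220 library of donor B, 0.081 CPM, was below the floor of 0.239 CPM. On GRCh38, IFIT1 (ENSG00000185745) lies on chromosome 10 from 89392546 to 89406487, and IFI44L (ENSG00000137959) and IFI44 (ENSG00000137965) are neighbours on chromosome 1, from 78619902 to 78646145 and from 78649796 to 78664078. IFI44L went from 45.2 ± 34.5 to 9.89 ± 4.81 CPM and IFI44 from 37.5 ± 18.1 to 14.8 ± 3.02 CPM (SD, n = 4). ISG15, a ubiquitin-like modifier, had 37.1 ± 19.7 CPM in DMSO and 15.5 ± 4.19 CPM in C220, and IRF7, the transcription factor that amplifies interferon production, had 32.7 ± 15.7 and 15.4 ± 8.99 CPM (SD, n = 4). The mean log2 fold change of the list was -0.70, with an adjusted p of 6.31e-15 by camera with a preset correlation of 0.01. With an estimated correlation of 0.371 between members the call was lost, at an adjusted p of 0.999. With the replicate block, camera gave an adjusted p of 6.4e-20 with the preset correlation and 0.889 with an estimated one. The list test fry gave adjusted p values of 0.997 without the block and 0.316 with it. Before adjustment over all lists tested, the p was 0.0715 by camera with the estimated correlation and no block. By fry the unadjusted p was 0.0945 without the block and 0.0264 with it, the latter a test chosen after seeing the data.

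Within donors, the mean log2 change of the list was -0.20 in donor A, -0.67 in donor B, -0.76 in donor C and -0.88 in donor D. The mean over donors was -0.63 ± 0.30 (SD, n = 4), and in the exact two-sided sign-flip permutation test 2 of the 16 sign assignments gave a mean as far from 0, the fewest possible with 4 donors, so this test could not pass the threshold. No member was called by edgeR over all genes tested. Adjusted over the list alone, edgeR called 4 members lower, IFIT1, IFI44L, IFI44 and IFI6, and none higher. With the donor as a replicate block, 29 members were called lower, adjusted over the list alone. Without donor B, C or D, in turn, the count without the block was 0, and with the block it was 33, 9 and 23.

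**Figure D1:**
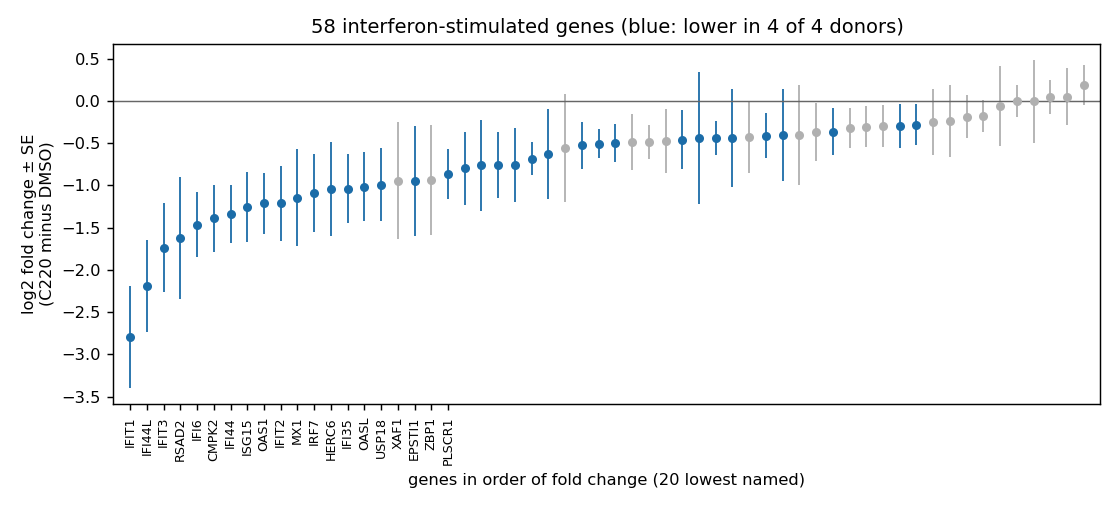
Log2 fold change of C220 minus DMSO with its standard error (y axis) for the 58 interferon-stimulated genes tested, in order of fold change (x axis, the 20 lowest named), from edgeR over 4 libraries per group. Blue points are the 36 members lower in C220 in 4 of 4 donors, and 55 of the 58 points lie below 0.

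**Figure D2:**
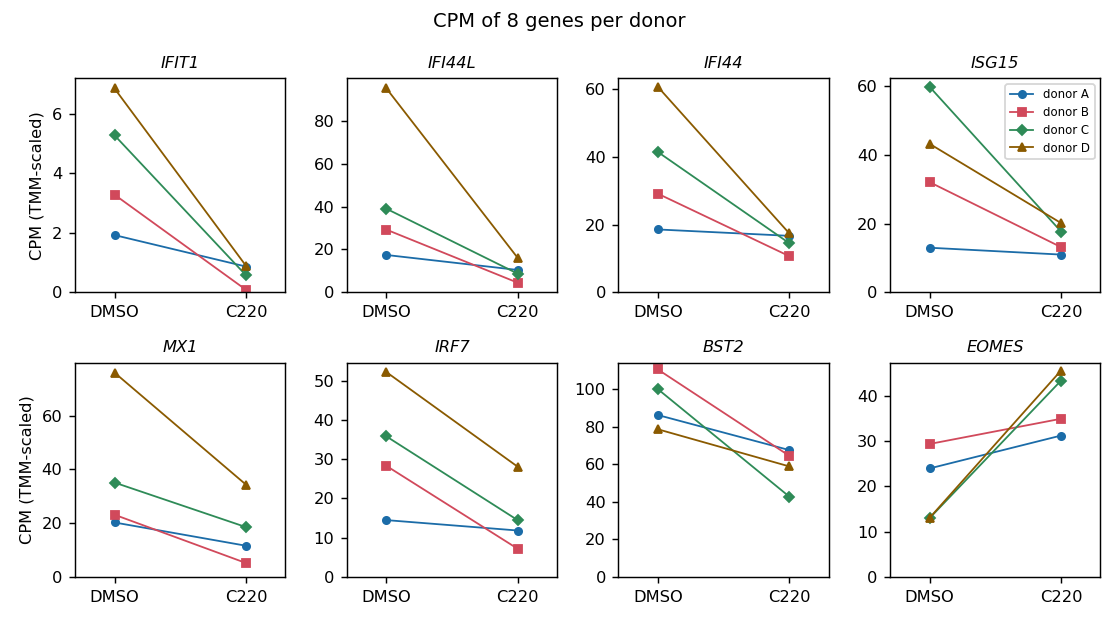
TMM-scaled CPM (y axis) of 8 genes in the DMSO and C220 libraries of each donor (x axis), with a line joining the libraries of 1 donor. IFIT1, IFI44L, IFI44, ISG15, MX1, IRF7 and BST2 were lower in C220 in 4 of 4 donors, and EOMES was higher in 4 of 4 donors.

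Across single genes, no difference passed the edgeR test without a donor block. Of 13706 genes tested, 0 were called higher and 0 lower, 488 had an unadjusted p under 0.05 where chance gives 685, and the smallest adjusted p was 0.905. limma-voom also called 0 higher and 0 lower, and DESeq2 called 1 higher, NBPF19, and 1 lower, IFIT1. With the replicate block, edgeR called 0 higher and 0 lower with 1629 genes at an unadjusted p under 0.05, and DESeq2 called 26 higher and 29 lower. Among the 8 ways to part all 4 donor pairs, the treatment gave the most genes at an unadjusted p under 0.05 in that edgeR fit. The next highest, which swapped donor D only, gave 1540, and the others gave 11 to 725. The 8 ways are too few for a share under 0.05, so the 1629 cannot set the treatment apart. Of the 29 genes that DESeq2 called lower with the block, 15 were members of the interferon-stimulated list. On 1 set of simulated counts DESeq2 with the replicate block made 27 false calls among 180, a false share of 15%. The simulated genes varied more evenly than the real ones, so the share need not hold for the real counts. Its single calls should be read with caution.

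Among the protein-coding genes that DESeq2 called lower with the replicate block, the largest falls on the log2 scale without the block were those of SAXO2, IFIT1, IFI44L, IFIT3 and RSAD2. SAXO2 was near the limit of detection in C220, with 3.84 ± 4.33 CPM in DMSO and 0.215 ± 0.231 CPM in C220 (SD, n = 4). Its DMSO level was also low in donors A and B (0.465 and 0.364 CPM), so its mean fall came mainly from donors C and D (5.11 and 9.43 CPM in DMSO). RSAD2, the antiviral enzyme viperin, had 45.1 ± 38.8 and 14.6 ± 6.88 CPM. GAA, the lysosomal enzyme that breaks down glycogen, was called lower with 18.2 ± 3.10 CPM in DMSO and 8.22 ± 2.39 CPM in C220. Among its protein-coding calls with at least 1 CPM in the higher group and the same direction in 4 of 4 donors, the largest rises belonged to JAKMIP1, COL6A3, MCTP2, NCR3LG1 and PIK3CG. PIK3CG, the catalytic subunit of phosphoinositide 3-kinase gamma, had 35.5 ± 17.2 CPM in DMSO and 73.4 ± 17.5 CPM in C220, and JAKMIP1 had 14.1 ± 0.880 and 35.7 ± 15.7 CPM (SD, n = 4). TNFSF4, the OX40 ligand, and CRTAM, a receptor of cytotoxic lymphocytes, were also called higher, from 9.35 ± 2.88 to 17.5 ± 5.76 CPM and from 90.01 ± 39.1 to 165.8 ± 8.98 CPM.

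Genes that respond mainly to interferon-gamma were not called as a list. The 26 members tested had a mean log2 change per donor of 0.03 ± 0.10 (SD, n = 4), and camera gave an adjusted p of 0.824. The interferon-stimulated list minus the interferon-gamma list gave a difference of -0.29 in donor A, -0.80 in donor B, -0.68 in donor C and -0.87 in donor D, with a mean of -0.66 ± 0.26 (SD, n = 4). In the exact sign-flip permutation test, 2 of the 16 sign assignments were as far from 0, again the fewest possible. IFNG itself had 206.6 ± 57.97 CPM in DMSO and 262.8 ± 117.8 CPM in C220, with 2 donors lower and 2 higher. With the replicate block and adjusted over the list alone, 2 members were called higher, among them ICAM1, the adhesion molecule for lymphocytes, at 41.8 ± 22.4 and 62.4 ± 29.1 CPM. The lists of interferon receptors and sensing genes (17 tested, adjusted p 0.998) and of MHC and antigen processing genes (27 tested, adjusted p 0.233) did not pass the camera test.

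Helper lineage transcription factors, which set the type of effector cell a T cell becomes, rose as a list in C220, with a mean log2 fold change of 0.25 over 20 members and an adjusted p of 0.0286 by camera. The adjusted p was 0.999 with an estimated correlation, and it rose to 0.0695 without donor D and to 0.194 without the C220 library of donor D. The members with the largest values were EOMES, a driver of cytotoxic programmes, PRDM1, which encodes Blimp-1, and RORA. EOMES had 19.8 ± 8.18 CPM in DMSO and 38.8 ± 6.82 CPM in C220 (SD, n = 4), and none of the 3 passed the test, adjusted over the list alone. The call was also lost without the DMSO library of donor A (adjusted p 0.18), the DMSO library of donor B (0.0508) or the C220 library of donor C (0.107).

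Cytokine, chemokine and cytotoxic genes gave no list call by camera without the replicate block over all 8 libraries. The lists of T cell cytokines (21 tested), chemokines and chemokine receptors (18 tested) and cytotoxic effector genes (20 tested) had camera adjusted p values of 0.981, 0.171 and 0.283. Without donor B, the chemokine list (adjusted p 0.000772) and the cytotoxic list (0.000152) were called higher, and of the 12 fits without the block that left out a donor or a library they were called in 2 and 4. Both were also called higher over all 8 libraries with the replicate block and the length and GC trend removed (0.00241 and 0.0442). With an estimated correlation neither was called, at an adjusted p of 0.999 each, and 0.96 each with the block. IL2 had 197.9 ± 89.4 CPM in DMSO and 126.7 ± 61.0 CPM in C220 (SD, n = 4), lower in 4 of 4 donors without passing the test, and TNF had 435.4 ± 184.4 and 396.9 ± 122.8 CPM. With the replicate block, adjusted over the list alone, IL17F, a cytokine of Th17 cells, was called lower at 6.69 ± 2.23 and 2.63 ± 1.63 CPM. In the same fit CCL20 was called lower among the chemokine genes, and 4 members, CCL22, CCR4, CCR8 and CX3CR1, were called higher. CCR4, a receptor for CCL22, had 202.7 ± 34.3 CPM in DMSO and 317.3 ± 54.8 CPM in C220. In donor A CCR4 barely changed, at 239 CPM in DMSO and 241 CPM in C220, and nor did CCL20 (32.4 and 32.1 CPM). The lists of activation and costimulation genes, naive and memory genes, common gamma chain signalling and T cell identity genes had adjusted p values of 0.43, 0.9, 0.727 and 0.88.

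The call of the mitosis genes depended on the fit and on single libraries. The 51 G2/M members tested had a camera adjusted p of 0.11, and of 8.48e-05 with the replicate block, which became 0.96 with the block and an estimated correlation. Fits without the block also called the list lower with library size only (adjusted p 0.0255), without donor C (0.00051), without the DMSO library of donor C (1.13e-08) or D (0.0109) and without the C220 library of donor B (9.61e-08). Their mean log2 change was -0.58 in donor A, -0.64 in donor B, -0.06 in donor C and 0.12 in donor D. Without the DMSO library of donor B, the list was called higher instead, with an adjusted p of 0.0317. That fit had no block and kept donor B in C220 only, so donor level and treatment are mixed in it. Without both libraries of donor B, camera called the list lower with the block (0.02) and did not call it without (0.137). MKI67, a marker of cycling cells, had 114.2 ± 76.9 CPM in DMSO and 115.1 ± 100.3 CPM in C220 (SD, n = 4). It was highest in donor B in both groups, at 198 and 261 CPM. Its near-equal means hid opposite changes, with a log2 change of -1.31 in donor A, 0.39 in B, 0.98 in C and 0.16 in D. The 43 G1/S and DNA replication genes and the 13 mitochondrially encoded transcripts had adjusted p values of 0.73 and 0.3. The p53 target genes had an adjusted p of 0.6, and CDKN1A, the p53-induced cell cycle inhibitor, had 57.9 ± 18.6 and 59.2 ± 20.6 CPM. The p53 list was called higher in 1 of the 12 fits without the block that left out a donor or a library (adjusted p 0.0127).

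PRMT5 itself, which an inhibitor of the enzyme need not alter, had 61.6 ± 22.8 CPM in DMSO and 67.8 ± 28.1 CPM in C220 (SD, n = 4). Its cofactor WDR77 had 28.4 ± 16.0 and 22.9 ± 8.24 CPM, and CLNS1A, the adaptor that brings Sm proteins to PRMT5, had 115.3 ± 39.5 and 98.7 ± 14.1 CPM. None of these differences passed the edgeR test. The PRMT family and PRMT5 partners, the snRNP and Sm assembly genes, the splicing regulators and the MYC targets and ribosome biogenesis genes had camera adjusted p values of 0.689, 0.11, 0.602 and 0.595. The snRNP list was called lower in 5 of the 12 fits without the block that left out a donor or a library (adjusted p 0.0402 without donor A), and the MYC list in 3. Cholesterol biosynthesis, glycolysis, the unfolded protein and integrated stress response and the apoptosis regulators had values of 0.11, 0.9, 0.283 and 0.233. The cholesterol list was called higher in 4 of those 12 fits (0.0349 without donor A) and with the replicate block and the length and GC trend removed (0.0333). The unfolded protein list was called lower in 1 of the 4 blocked fits that left out a donor (0.0123). With an estimated correlation, the snRNP, MYC and cholesterol lists each had an adjusted p of 0.999. With the block and an estimated correlation they had 0.96, 0.96 and 0.93.

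**Figure D3:**
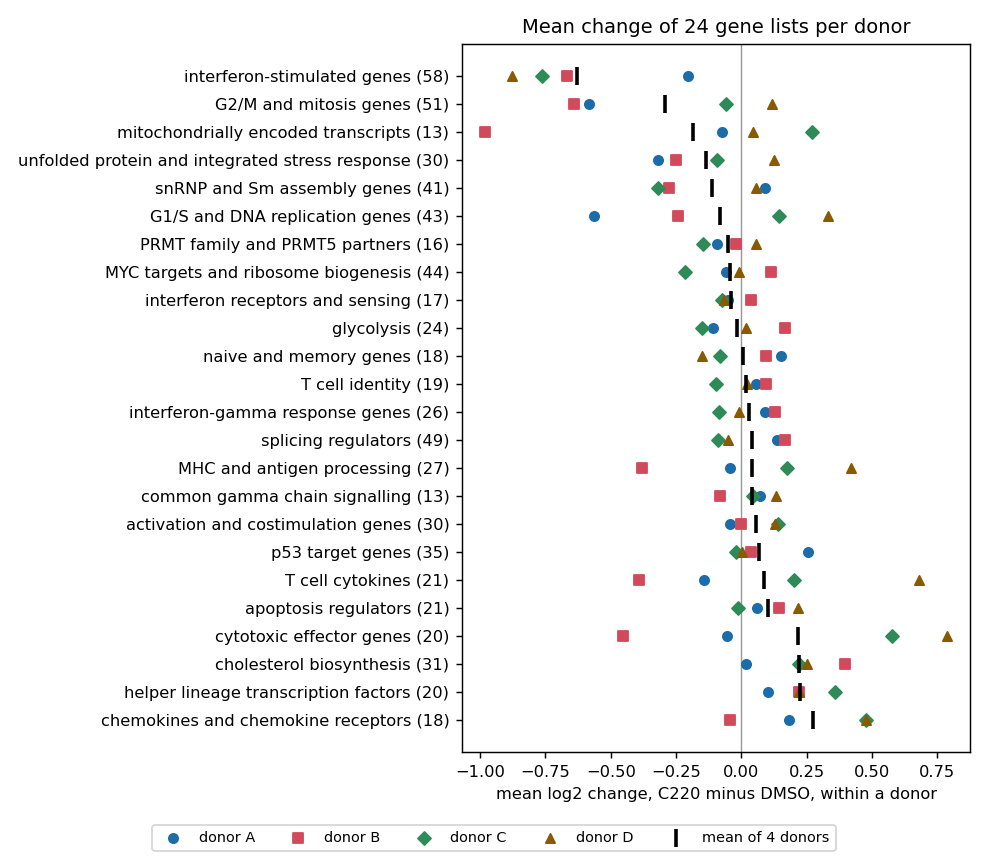
Mean log2 change of C220 minus DMSO within each donor (x axis) for the 24 gene lists with enough members tested (y axis, number of members in brackets), with a symbol per donor and a bar at the mean of 4 donors. The interferon-stimulated list had a mean of -0.63, with 4 of 4 donors below 0.

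Markers of other blood cells were scarce. At a mean of at least 20 counts, 3 of 12 B cell markers, 2 of 18 monocyte and macrophage markers, 3 of 10 dendritic cell markers, 3 of 13 NK cell markers and 1 of 11 platelet and red cell markers could be tested, too few for a list test. The 3 B cell markers had log2 fold changes from -1.89 to -0.07, and none was called. Their mean log2 change was -0.05 in donor A, 0.10 in donor B, -1.12 in donor C and -0.79 in donor D. AIF1, a gene of monocytes and macrophages, was called lower with the replicate block, adjusted over only the 2 members of its list that could be tested, at 9.67 ± 6.17 CPM in DMSO and 4.61 ± 3.67 CPM in C220 (SD, n = 4). The other member, LYZ, had a log2 fold change of 1.03 and passed no test. The mean log2 change of the 2 members was 2.49 in donor A, -1.09 in B, -1.69 in C and -0.66 in D. AIF1 had -0.16 in donor A, so the rise of LYZ came mainly from that donor. The summed level of 15 other markers of monocytes, dendritic cells and B cells, chosen after values were seen and without AIF1, ranged from 3.55 to 9.56 CPM in the DMSO libraries and from 2.78 to 12.3 CPM in the C220 libraries. With AIF1 the sum ranged from 10.1 to 23.5 CPM in DMSO and from 3.86 to 19.4 CPM in C220. All 40 members of the preset lists of these 3 cell types summed to 165 to 240 CPM in DMSO and 157 to 230 CPM in C220, the largest part from CD83, at 96.7 to 142 CPM in the DMSO libraries.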

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

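The tests of gene length and GC bias, of the DMSO library of donor B and of other cells as accounts of the interferon-stimulated genes were chosen only after the result was seen. Of 165 sets of 4 values, 7 held a value far from the other 3, where chance gives about 1 in 20, or 8.

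The DMSO library of donor B had 5.84% of its counts on mitochondrial genes, against 2.22 to 2.6% in the other DMSO libraries, and a mean correlation of 0.917 with the other 7 libraries, against 0.948 to 0.953. Removing each library's trend on gene length and GC content raised its correlation to 0.927, still below the lowest other value of 0.951, which argues against that trend as the whole source. Leaving out the mitochondrial genes gave 0.917, but so few genes cannot move a correlation, so this decided nothing. No biological explanation was tested.

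The other distant values were PRMT5 in the DMSO library of donor A (95.7 CPM, others 48.0 to 51.6), IL2 in the C220 library of donor A (218 CPM, others 90.8 to 102), MTSS1 in the C220 library of donor C (47.9 CPM, others 27.4 to 29.9), the log2 change of IL2 in donor B (-1.23, others -0.48 to -0.39) and that of RORA in donor C (1.5, others 0.46 to 0.53).

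The fall of the interferon-stimulated genes is the pattern most worth a second look. With the length and GC trend removed, the mean change over donors was -0.659, and over donors A, C and D it was -0.615, against -0.628 uncorrected in all 4 donors, so neither that trend nor the odd library of donor B accounts for it. The T cells were negatively selected, a step meant to remove other blood cells. A loss of remaining monocytes, dendritic cells or B cells nevertheless stays open. In DMSO, 15 of their markers summed to at most 2.36% of the summed fall of the list in any donor, and 6.43% with AIF1. All 40 preset markers summed to 73.8%, 52.6%, 22.1% and 11.1% of it in donors A to D, the largest part from CD83. Bulk counts cannot tell whether the CD83 reads came from T cells or from other cells. From DMSO to C220 these 40 went from 165 to 192 CPM in donor A, 193 to 157 in B, 240 to 199 in C and 235 to 230 in D, and the 15 from 5.29 to 12.1, 4.79 to 2.82, 3.55 to 2.78 and 9.56 to 12.3 CPM. With AIF1 the 15 went from 13.4 to 19.4, 23.5 to 11.1, 10.1 to 3.86 and 14.8 to 14.1 CPM. All 3 sums were thus higher in C220 in donor A, where the list fell least, and lower in B and C. This goes in part with the explanation, although the list fell in donor A as well. In donor D the list fell most, by 2120 summed CPM, yet 2 of the 3 sums were only slightly lower and the 15 alone were higher. The sums of donor D thus go against the explanation. The markers are few and low in counts, and the level of CD83 would hide a small share, so no sum settles it. Chance could not be excluded. Of the 35 splits of the 8 libraries, 2 gave a camera p as small as the real 2.63e-16, the real split and 1 other. The other, with 1.94e-21, was a split that parted 2 of the 4 donor pairs. It set both libraries of donor D against both of donor B, so donor level and treatment are mixed in it. Among the other splits that part all 4 pairs the smallest was 2.9e-14. That split swapped the treatment in donor A only, where the list fell least, so it still largely compares the treatments. The split with 1.94e-21 also parted donors A and C by treatment, so neither value measures chance alone. The splits with the treatment swapped in 2 of the 4 donors gave 0.000294, 2.3e-05 and 0.431. A change shared by all donors cancels in them, yet 2 of these values were small. Camera with the preset correlation thus gave small p values even where the treatment was balanced, so the real one overstates the evidence. The 8 splits that part all 4 donor pairs are too few for a share under 0.05; 1 of the 8, the real one, called 29 members adjusted over the list alone with the replicate block, and the highest other called 0. A response of the cells to PRMT5 inhibition remains open as a hypothesis.

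For the count of genes called, the splits decide nothing, since the real split called 0 genes and 35 of 35 splits necessarily called as many. The highest other called 3518. That split parted none of the donor pairs, which points to a structure among donors larger than the treatment.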

How the results depend on the processing

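Tests with the length and GC trend removed, robust fits and the blocked camera variant with an estimated correlation and blocked fry were chosen after seeing the data. The interferon-stimulated list stayed lower and past the threshold under every scaling, filter and left-out donor or library (adjusted p at most 3.1e-05, and 6.91e-10 with donors left out of the blocked fit), but not with an estimated correlation (0.999, 0.889 with the replicate block) or fry (0.997, 0.316 with the block). Its mean change ranged from -0.769 to -0.544, and the median over members in place of the mean gave -0.537. The helper lineage list was lost under the same 4 settings (0.999, 0.889, 0.997 and 0.316), and ranged from 0.00108 to 0.194 as donors or libraries were left out without the block, and from 0.000616 to 0.0419 as donors were left out with it. Lists called higher and lower, 1 and 1, became 0 and 0 under those 4 settings; lower lists became 2 with the replicate block, 2 with library size only, and with the block and trend removed 4 were higher (helper lineage, chemokine, cytotoxic and cholesterol) and 2 lower. Leaving out donors or libraries gave 0 to 5 higher and 1 to 5 lower, and with the block, 1 to 4 higher and 2 to 5 lower. Without the DMSO library of donor B, the lists of G1/S (adjusted p 0.00665), G2/M (0.0317) and mitochondrially encoded genes (0.0151) turned from lower to higher; as donors or libraries were left out, their adjusted p ranged from 5.46e-05 to 0.991, from 1.13e-08 to 0.717 and from 0.00584 to 0.681 without the block, and from 0.0123 to 0.988, from 4.67e-09 to 0.0705 and from 0.00463 to 0.332 with it. Leaving out 1 library without the block keeps its donor in 1 group only, so donor level and treatment are mixed in that fit. The cause was not tested. The 0 genes called became 5 lower without a filter, 1 higher and 1 lower with DESeq2, and 26 higher and 29 lower with DESeq2 and the replicate block; leaving out donors or libraries gave 0 and 0, and with the block 0 to 1 higher and 0 to 1 lower. The 4 interferon-stimulated members called, adjusted over the list alone, became 29 with the replicate block, 36 with block and trend removed, 0 with library size only, 22 without a filter, 0 at 100 counts, 12 with DESeq2, 30 with DESeq2 and block, 0 with limma-voom, 0 to 15 as donors or libraries were left out without the block, and 9 to 33 as donors were left out with it. The causes were not tested. Signs changed in 30 of 1155 values of named genes and 76 of 672 of lists, and apart from the 3 lists above no call was involved. Depth limits what can be said of genes near 20 counts.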

Other observations

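The test of snoRNA host transcripts was chosen only after their values were seen.

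Transcripts of type I interferon itself were at the edge of detection. IFNB1, which encodes interferon beta, had 33 counts over the DMSO libraries and 13 over the C220 libraries, a depth-scaled ratio of 0.428 (95% exact interval 0.207 to 0.836, counting error only), and was lower in C220 in each donor. In donors A to D it had 2, 18, 8 and 5 counts in DMSO and 1, 6, 3 and 3 in C220. The pooled ratio thus leans on the DMSO library of donor B, which stood apart from the others and held 18 of the 33 counts. The other 18 interferon alpha, lambda and omega genes examined had 24 and 18 counts in all.

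Changes were only partly shared between donors. Across genes, which are not independent replicates, log2 changes correlated at 0.354 between donors A and B, 0.453 between C and D, 0.496 between B and C, 0.121 between A and C, -0.106 between A and D and -0.103 between B and D.

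A hypothesis formed from the low counts of SNHG5 was that snoRNA host transcripts may fall together in C220. Their mean log2 change over 12 transcripts was -0.08 in donor A, -0.94 in donor B, -0.69 in donor C and -0.0411 in donor D, and 3 of the 12 were lower in 4 of 4 donors. The size differed so much between donors that the test left the hypothesis open.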
